A study of Sus scrofa with 12 samples.

How the data were processed

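Left ventricular myocardium of pigs was profiled on an Affymetrix porcine gene array, with 12 arrays in 4 groups of 3. The groups were the free wall and the septum of control animals, and the same 2 regions of animals with ablated atrioventricular conduction and a pacemaker that sensed the atrium and paced the right ventricular septum. Per the labels, the animals were 13 months old, tissue was taken 6 months after surgery, total RNA was extracted with Trizol and the label was biotin. The design text names 6 female pigs per arm, while 3 arrays per group were analysed here.

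The deposited values are log2 intensities, 1 per probe set and array, which the authors made with Affymetrix Expression Console 1.4 and RMA, per the submitters' processing notes. RMA corrects the background, normalizes arrays to each other by quantiles and summarises the probes of a set on the log2 scale. Scanner files were not analysed here, so neither background nor detection of a probe set could be checked, and the genome build and annotation behind the array are not given in the sources used here. The table held 27558 probe sets with values from 0.45 to 13.14, and array medians lay between 4.305 and 4.45. No source used here marks control probe sets, so the tests ran on all of them. Among the probe sets, 1239 had the same 12 values as another one and were kept.

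Gene names came from the platform annotation. It gave 1 gene symbol for 13157 probe sets, several symbols for 523 and no gene for 13878. Of the probe sets with 1 symbol, 12841 were matched by gene ID to a reference gene table of assembly Sscrofa11.1, which updated 7 symbols. Probe sets with several symbols were not named, and no coordinates were used. The named probe sets covered 12217 genes, of which 881 had several probe sets.

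Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), with all 12 arrays in 1 fit so that the 4 groups shared an estimate of the spread. Adjusted p-values follow Benjamini and Hochberg over all probe sets, with a threshold of 0.05. The 7 comparisons were paced against control in the free wall, in the septum and averaged over both, septum against free wall in control animals, in paced animals and averaged over both, and the difference between the effects of pacing in the 2 regions. For the effect of pacing averaged over both regions, the free wall and septum arrays of the same group and number were averaged first, which left 3 values per arm. In paced animals these pairs rest on the numbers alone.

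Gene groups were tested with limma's camera at a preset correlation of 0.01 on 45 lists, 13 of them markers of cell types or chambers, each with at least 5 measured members. The probe set with the highest mean stood for each gene, and adjustment was over the 45 lists of a comparison. Camera with an estimated correlation and limma's fry were run beside it. Member counts are given over all probe sets and adjusted over the list alone. The latter adjustment does not cover the 45 lists, so chance can give a few such members in each comparison.

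The comparisons, tests, lists, a panel of 24 heart genes (20 of them measured) and the rule for the genes named were fixed before the data were examined. The rule took, for 5 of the comparisons (all but those between regions within control or within paced animals), the 8 highest and 8 lowest changes past the threshold among probe sets with 1 symbol, filled with the smallest unadjusted p where fewer passed. It left out symbols that start with LOC or are only an accession, and took for a gene the probe set with the smallest p. It added the 3 members with the smallest p of each list past the threshold (at least 3 lists, at most 8) and, for pacing, the panel, with the probe set of the highest mean for each of these genes. The text names a part of these, and says where a gene was chosen after its values were seen.

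The scripts were tested on simulated arrays with the means and spreads of these arrays. Of 200 probe sets above the median with a log2 change of 1, limma recovered 72.5% for pacing in the free wall, 75% in the septum, 80.5% averaged over both regions, 70% for septum against free wall in control animals, 77% in paced animals, 92.5% averaged over both arms and 32.5% for the difference between the effects. At a log2 change of 0.5 it recovered 37% for septum against free wall averaged over both arms and 0% in the other 6 comparisons. These shares hold for 200 changes at once with noise drawn separately for each array. Fewer true changes make the adjusted threshold stricter, so the shares are not the power for these data. In the real free wall comparison, 102 probe sets differed by 1 or more between paced and control animals, and 1 passed. A shift of 0.5 in 1 simulated list, the extracellular matrix genes, was found by camera with an adjusted p of 1.57e-24. The simulated genes varied independently of each other. In the real arrays the estimated correlation was 0.203 for this list and 0.493 for interferon response genes. The simulation therefore does not test camera where the members of a list vary together.

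Array numbers in the labels recur in each group. In control animals, free wall and septum arrays of the same number deviated together from their group means, with correlations of 0.453, 0.344 and 0.358 across probe sets above the median, so the numbers pair these samples; blocking on them left 0 probe sets between the regions of control animals, as in the fit without the block. The alternatives were a replicate block, other ways to treat the animal, only the groups compared, only bright probe sets, quantile normalization, median centring, eBayes with trend and robust, array weights, leaving out each array (for pacing averaged over the regions, the 2 arrays of a number and arm), and, for genes and lists, the mean of all probe sets of a gene. Replicates are numbered arrays, and nothing in the labels states that each came from a separate animal, so the p-values measure the spread between these arrays. The number of arrays limits the precision.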

Results

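Messenger RNA levels were measured in the left ventricle of pigs, in the free wall and in the septum at the level of the papillary muscles. Control animals were compared with animals that had lived 6 months with atrioventricular block and a pacemaker in VDD mode, which senses the atrium and paces the ventricle. Pacing stands below for the block and the pacemaker together, which the groups do not separate. The ventricular lead sat on the right ventricular septum, so the septum lay at the pacing site and the free wall away from it. Each of the 4 groups had 3 arrays. The stated aim was to find how RNA levels differ between the free wall and the septum. Levels are log2 intensities, and a difference of 1 is a 2-fold difference. The median standard error of a difference was 0.165 between 2 groups of 3 arrays, 0.114 for pacing averaged over the regions, 0.117 for the regions averaged over the arms and 0.234 for the difference between the effects of pacing.

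In the septum, CCK, which encodes the peptide hormone cholecystokinin, was lower in paced animals. CCK stood at 10.6 ± 0.367 (SD, n = 3) in control animals and at 8.71 ± 0.283 (SD, n = 3) in paced animals. It fell by 1.92 on the log2 scale (SE 0.223, limma adjusted p = 0.0286), and all 3 paced arrays lay below all 3 control arrays. An unnamed probe set, 15342515, fell by 3.65 (SE 0.332, adjusted p = 0.00423). It has no gene in the annotation, lies outside the rule for named genes and was chosen after its values were seen. These were the 2 of 27558 probe sets that passed in the septum, against 1223 at an unadjusted p under 0.05, where chance gives 1378 on average. Such counts vary widely, and other splits of the septum arrays into 3 and 3 gave 555 to 1939. The call for CCK ended in 8 of 12 fits with 1 array left out, with adjusted p from 0.0186 to 0.272 and log2 differences from -2.13 to -1.79 over the 12. Those 8 left out free wall control array 2, any free wall paced array, septum control arrays 2 and 3 or septum paced arrays 2 and 3, and the call also ended in a fit of the 2 septum groups alone (log2 difference -1.92, adjusted p = 0.286, with a range of 0.00998 to 0.559 over all alternatives). The call for probe set 15342515 ended without septum paced array 3 (adjusted p = 0.0505, differences from -3.70 to -3.59 over the 12 fits).

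Other septum genes with small p did not pass. PDZD9 differed by -0.99 (SE 0.158, adjusted p = 0.393), XKRX by -1.67 (SE 0.347) and the purinergic receptor gene P2RY1 by -1.07 (SE 0.224). NRSN1 differed by -1.60 (SE 0.371) and the transcription factor gene FOXC2 by -0.80 (SE 0.183). On the higher side were the prostaglandin F receptor gene PTGFR at 1.43 (SE 0.269), FAM169A at 0.98 (SE 0.187), the potassium channel gene KCNA5 at 0.89 (SE 0.204), the growth factor gene EREG at 0.88 (SE 0.183), FLRT3 at 0.71 (SE 0.138) and 1 probe set of DOCK8 at 0.67 (SE 0.137). Each of these 6 had an adjusted p of 0.763, and each separated all paced from all control arrays, which chance gives for 10% of probe sets. The brightest probe set of DOCK8 differed by 0.01 (SE 0.227).

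Ribosomal protein genes were the list that passed in the septum. Of 38 measured members 31 were higher in paced animals, with a median difference of 0.07 and camera adjusted p = 0.0315 (adjusted p = 0.884 with an estimated correlation, and 0.808 with fry). No member passed over all probe sets and 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05. RPLP2 differed by 0.43 (SE 0.152), RPS25 by 0.24 (SE 0.106) and RPL10A by 0.20 (SE 0.111), or 0.06 in the mean of its probe sets. The camera call ended without septum control array 1 or 3 or without septum paced array 2, with adjusted p up to 0.357. Glucose use genes did not pass (adjusted p = 0.284), with ALDOC, a glycolytic aldolase, at -0.70 (SE 0.196) and HK2, a hexokinase, at -0.70 (SE 0.327). Neither did genes of TGF-beta signalling (adjusted p = 0.418), among which TGFBI differed by 0.67 (SE 0.230). Adjusted over the list alone, 1 of 23 ion channel and gap junction genes passed, KCNA5, and 1 of 25 mechanosensing and cytoskeleton genes, SGCA, which encodes alpha-sarcoglycan, at 0.53 (SE 0.124). SGCA was chosen here after its values were seen.

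In the free wall, no named gene passed for pacing. Probe set 15342515 stood at 6.65 ± 0.080 (SD, n = 3) in control animals and 3.64 ± 0.935 (SD, n = 3) in paced animals and fell by 3.01 (SE 0.332, adjusted p = 0.0324). It was the 1 probe set that passed, with 1292 at an unadjusted p under 0.05. PDZD9 differed by -1.08 (SE 0.158, adjusted p = 0.130). MSR1, a scavenger receptor gene of macrophages, differed by -0.89 (SE 0.160, adjusted p = 0.365), NSMCE1 by -0.70 (SE 0.155) and EMP2 by -0.62 (SE 0.151). TP53I13 differed by 0.80 (SE 0.134, adjusted p = 0.275), HS3ST5 by 0.69 (SE 0.167), TBC1D19 by 0.67 (SE 0.176) and ABCC4, an exporter of cyclic nucleotides, by 0.58 (SE 0.110). CCK, chosen here after its values were seen, differed by -0.54 (SE 0.223, adjusted p = 0.998). The call for probe set 15342515 ended in 10 of 12 fits with 1 array left out (adjusted p up to 0.292, differences from -3.48 to -2.54) and was kept without free wall paced array 2 or 3. It also ended in a fit of the 2 free wall groups alone (adjusted p = 0.460, with a range of 0.000278 to 0.704 over all alternatives).

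Interferon response genes were the list that passed in the free wall. Of 22 measured members 19 were lower in paced animals, with a median difference of -0.24 and camera adjusted p = 0.0284 (adjusted p = 0.952 with an estimated correlation, and 0.979 with fry). No member passed over all probe sets and 0 adjusted over the list alone. USP18 differed by -0.79 (SE 0.292), IFIT3 by -0.51 (SE 0.309) and STAT2 by -0.23 (SE 0.117). List scores ranged from -0.30 to 0.38 over the 3 control arrays and from -0.35 to 0.21 over the 3 paced arrays. The call ended without free wall control array 2 or 3 or without free wall paced array 1 or 2, with adjusted p up to 0.471. Macrophage markers did not pass in the same comparison (adjusted p = 0.141). Among them C1QC differed by -0.64 (SE 0.203) and C1QA by -0.28 (SE 0.131), both genes of complement component C1q. Autophagy and proteolysis genes did not pass either (adjusted p = 0.193), with the ubiquitin ligase gene FBXO32 at -0.42 (SE 0.199) and FOXO1 at -0.40 (SE 0.176).

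Averaged over both regions, 1 probe set passed for pacing, and no named gene did. Probe set 15342515 fell by 3.33 (SE 0.228, adjusted p = 0.0142), and 1445 probe sets had an unadjusted p under 0.05. This average joins free wall and septum arrays of the same number, and the paced arrays so joined did not deviate together, so the errors and p-values rest on pairs that the values do not bear out. XKRX differed by -1.49 (SE 0.190), CCK by -1.23 (SE 0.168), PDZD9 by -1.04 (SE 0.136) and NSMCE1 by -0.66 (SE 0.0897), each with adjusted p = 0.248. For these 4 genes every paced array lay below every control array. The serotonin transporter gene SLC6A4 differed by -1.01 (SE 0.159), ALDH5A1, an enzyme of GABA breakdown, by -0.77 (SE 0.123) and EPHX2, the soluble epoxide hydrolase gene, by -0.62 (SE 0.0958). PTGFR differed by 1.10 (SE 0.206), TBC1D19 by 0.73 (SE 0.117), LGALS3, the galectin-3 gene, by 0.55 (SE 0.118) and SGCA by 0.43 (SE 0.0903). The call for probe set 15342515 ended without the control arrays numbered 2 (adjusted p = 0.0759) or 3 (0.0745) or the paced arrays numbered 1 (0.105), the highest over all alternatives, whose lowest was 0.000255. Its difference lay between -3.59 and -3.07 in the 6 fits that left out arrays. With all 12 arrays as separate samples and no block, 4 probe sets passed, among them PDZD9 (adjusted p = 0.0122, with a range of 0.0122 to 0.668 over its alternatives) and CCK (adjusted p = 0.0486, with a range of 0.0305 to 0.668). That fit counts control arrays of the same number, taken here as pairs, as separate samples. With the animal as a random block PDZD9 passed (adjusted p = 0.0126) and CCK did not (adjusted p = 0.0532). That block used a correlation of 0.016 between arrays of the same number and arm, paced ones included. It therefore also treated the arrays as nearly separate samples. The lowest for CCK came without the control arrays numbered 1.

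None of the 20 measured panel genes passed for pacing. AGT, the angiotensinogen gene, differed by -0.69 averaged over both regions (SE 0.184, adjusted p = 0.836), by -0.74 in the free wall (SE 0.237) and by -0.65 in the septum (SE 0.237). KCNIP2, which encodes a subunit of the transient outward potassium channel, differed by -0.38 (SE 0.0928, adjusted p = 0.730), by -0.43 in the free wall (SE 0.112) and by -0.33 in the septum (SE 0.112). All paced arrays lay below all control arrays for both genes. The natriuretic peptide gene NPPB differed by -0.28 (SE 0.166) and NPPA by -0.23 (SE 0.536), the slow myosin gene MYH7 by -0.04 (SE 0.0803) and ANKRD1 by -0.20 (SE 0.112), each averaged over both regions. The collagen genes COL1A1 and COL3A1 differed by 0.30 (SE 0.224) and 0.47 (SE 0.418). NPPA stood at 0.43 without the control arrays numbered 3, and COL3A1 at -0.079 without those numbered 1. PDK4, a regulator of glucose oxidation, differed by -0.48 (SE 0.245) and SLC2A4, the insulin-responsive glucose transporter gene, by -0.36 (SE 0.174).

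**Figure D1:**
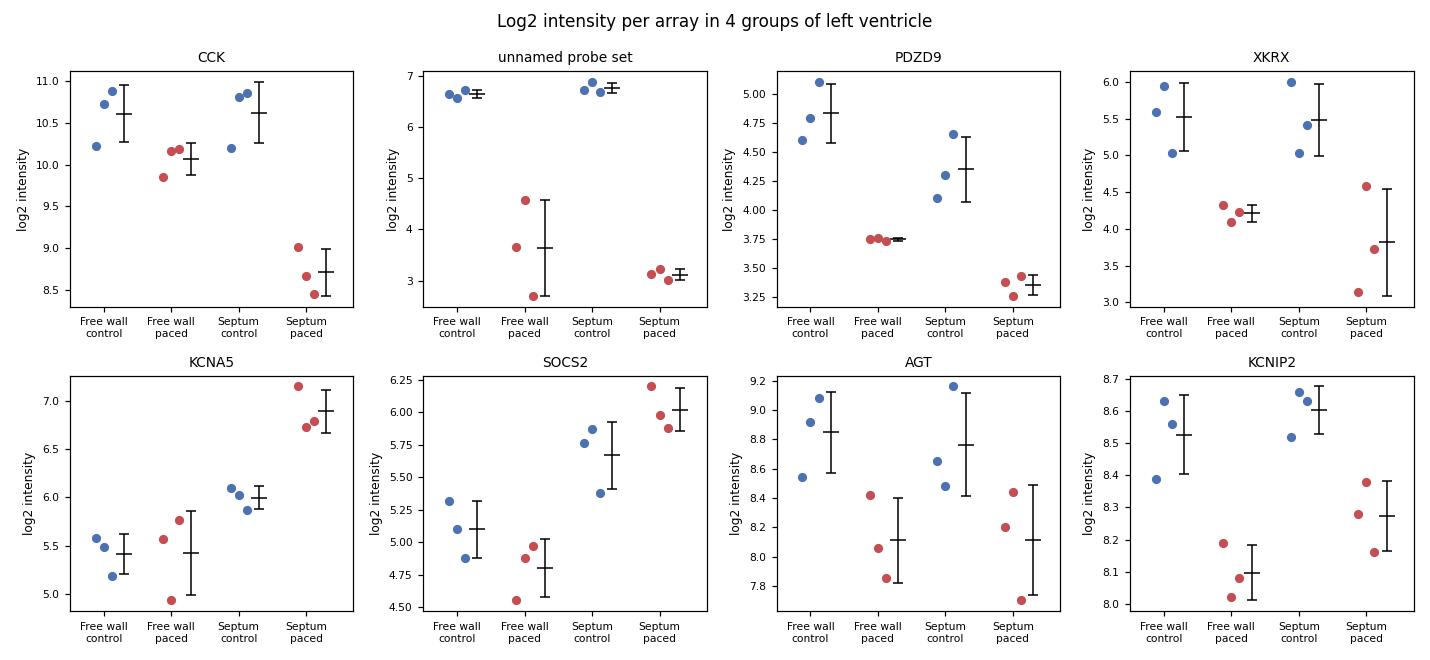
Log2 intensity (vertical axis) of 7 genes and probe set 15342515 on each of the 3 arrays per group (points), with the mean and SD of the group (bars). CCK averaged 10.6 in septum of control animals and 8.71 in septum of paced animals, and KCNA5 was higher in all septum than in all free wall arrays.

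No list passed for pacing averaged over both regions with camera, with an estimated correlation or with fry, and 6 of 45 had an unadjusted camera p under 0.05. Glucose use genes had 14 of 23 members lower (adjusted p = 0.0644), with ALDOC at -0.49 (SE 0.142), HK2 at -0.53 (SE 0.187) and GPI at -0.33 (SE 0.103). Interferon response genes had 20 of 22 lower (adjusted p = 0.0644) and ribosomal protein genes 28 of 38 higher (adjusted p = 0.0819). Of the 16 natriuretic and fetal program genes 13 were lower (adjusted p = 0.401). Adjusted over the list alone 2 of these 16 passed, NPR3, the natriuretic peptide clearance receptor gene, at -0.59 (SE 0.144) and XIRP2, an actin-binding protein gene of muscle, at 0.68 (SE 0.184). Both were chosen after their values were seen. Of 25 mechanosensing and cytoskeleton genes 1 passed adjusted over the list alone, SGCA. This adjustment does not cover the 45 lists, and chance is not excluded for these 3 genes. Extracellular matrix genes had 22 of 36 members higher (adjusted p = 0.466), calcium handling genes 11 of 16 lower (adjusted p = 0.638) and oxidative phosphorylation genes 27 of 43 lower (adjusted p = 0.466). None of the 13 marker lists passed, and the lowest adjusted p among them was 0.285, for smooth muscle and pericytes.

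**Figure D2:**
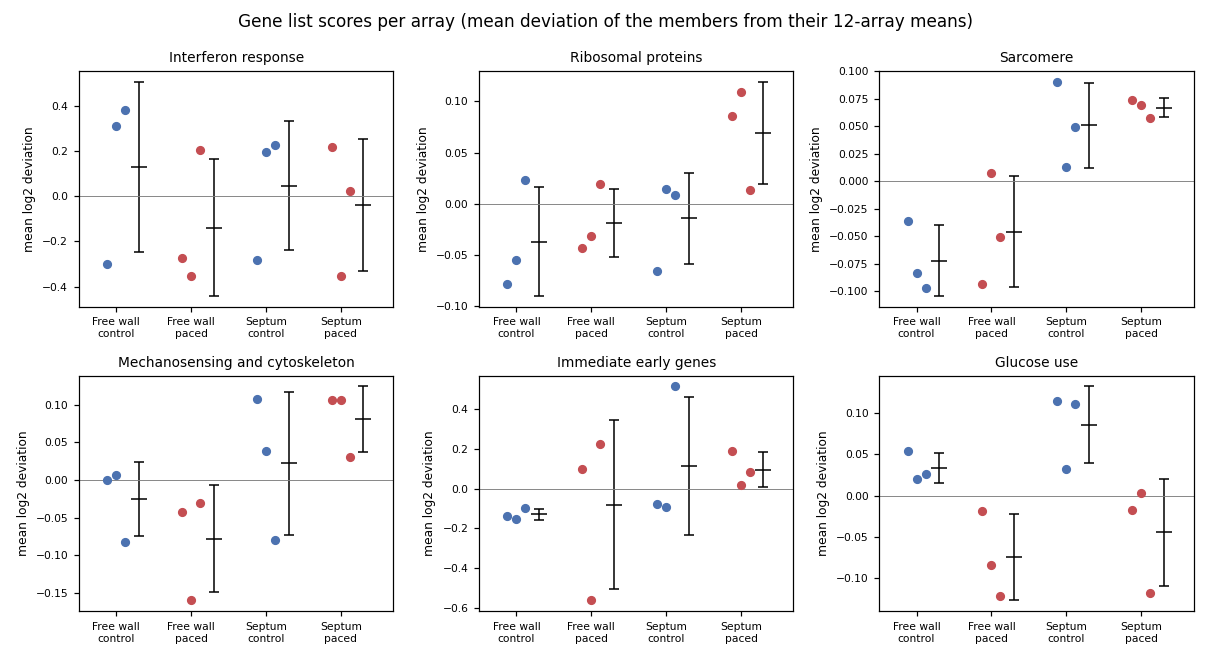
Score of 6 gene lists on each array (points), the mean log2 deviation of the members from their means over 12 arrays (vertical axis), with the mean and SD of each group of 3 arrays (bars). Sarcomere scores averaged -0.07 and -0.05 in free wall and 0.05 and 0.07 in septum of control and paced animals.

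Septum and free wall were compared next, averaged over control and paced animals. LOC100737875, a gene without a name, fell by 1.09 from free wall to septum (SE 0.122, adjusted p = 0.0382), and the unnamed probe set 15347989 fell by 0.81 (SE 0.0969, adjusted p = 0.0382). Both were chosen after their values were seen. These were the 2 probe sets that passed, with 1968 at an unadjusted p under 0.05. Other splits of the arrays within each arm gave 439 to 4551 at that level. KCNA5 was at 5.41 ± 0.208 and 5.42 ± 0.435 (SD, n = 3 each) in free wall of control and paced animals, and at 6.00 ± 0.117 and 6.89 ± 0.227 (SD, n = 3 each) in septum. Its difference of 1.03 (SE 0.144) did not pass (adjusted p = 0.0935), nor did those of SOCS2, a suppressor of cytokine signalling, at 0.90 (SE 0.121, adjusted p = 0.0881), RNF144B at 1.08 (SE 0.167, adjusted p = 0.130) and PDIA2 at 0.66 (SE 0.0971, adjusted p = 0.114). With the 13157 probe sets of 1 gene symbol alone, an alternative chosen after the data were seen, LOC100737875 and these 4 genes passed, with adjusted p from 0.00886 to 0.0499. With array weights, KCNA5 and SOCS2 passed (adjusted p = 0.0284 for both, where the alternatives reached 0.361 for KCNA5 and 0.331 for SOCS2). PDIA2 passed without free wall control array 2 (adjusted p = 0.0461), and the mean of its probe sets differed by 0.33 (adjusted p = 0.435).

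Further genes did not pass between the regions. The cyclin gene CCNY differed by 0.47 (SE 0.0826), STX6 by 0.69 (SE 0.124) and the interleukin-4 receptor gene IL4R by 0.59 (SE 0.107), each higher in septum with adjusted p = 0.271. The neurotrophin receptor gene NTRK2 differed by -0.92 (SE 0.217) in the probe set the rule took and by -0.76 (SE 0.247) in its brightest, CCK by -0.67 (SE 0.158) and ABCC4 by -0.39 (SE 0.0779). The call for LOC100737875 ended in 10 of 12 fits with 1 array left out (adjusted p up to 0.195, differences from -1.17 to -1.03) and was kept without free wall control array 2 or septum control array 3. The call for probe set 15347989 ended in 11 of 12 (adjusted p up to 0.195, differences from -0.88 to -0.76) and was kept without free wall control array 2. It also ended with quantile normalization (adjusted p = 0.101), median centring (0.0531) and eBayes with trend and robust (0.0572), with a range of 0.015 to 0.195 over all alternatives. The replicate block ended both calls (adjusted p = 0.0968 for LOC100737875, range 0.00886 to 0.195, and 0.159 for probe set 15347989). Its numbers were taken to pair the control arrays, while paced arrays of the same number did not deviate together.

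Sarcomere, mechanosensing and immediate early genes were the 3 lists that passed between the regions, all higher in septum. Of 19 sarcomere genes 17 were higher, with a median of 0.10 and camera adjusted p = 0.0173 (adjusted p = 0.501 with an estimated correlation, and 0.0222 with fry). Camera kept this call in all 12 fits with 1 array left out, with adjusted p up to 0.0420. MYOM2, a protein gene of the M band, differed by 0.49 (SE 0.111), LDB3 by 0.34 (SE 0.118) and MYBPC3, the cardiac myosin-binding protein C gene, by 0.28 (SE 0.0850). Over all probe sets 0 of the 19 passed, and adjusted over the list alone 1 did, MYOM2. Of 25 mechanosensing and cytoskeleton genes 20 were higher, with a median of 0.09 and adjusted p = 0.0345 (adjusted p = 0.501 with an estimated correlation, and 0.121 with fry). SGCA differed by 0.33 (SE 0.0875), CSRP3, the muscle LIM protein gene, by 0.25 (SE 0.0933) and TLN2 by 0.24 (SE 0.0840). Of 15 immediate early genes 13 were higher, with a median of 0.25 and adjusted p = 0.0403 (adjusted p = 0.697 with an estimated correlation, and 0.439 with fry). ZFP36 differed by 0.33 (SE 0.164), JUN by 0.32 (SE 0.106) and FOS by 0.25 (SE 0.106). In these last 2 lists 0 members passed over all probe sets and 0 adjusted over the list alone. The mechanosensing call ended without any of 5 arrays (adjusted p up to 0.259), namely free wall control 3, free wall paced 2, septum control 1 and septum paced 1 and 2. The immediate early call ended without any of 5 arrays (adjusted p up to 0.581), namely free wall control 1 and 2, free wall paced 2, septum control 3 and septum paced 1.

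Genes outside the naming rule passed adjusted over a list alone between the regions, and were chosen after their values were seen. The transcription factor gene GATA6 differed by 0.55 (SE 0.115) and passed in the hypertrophic signalling and the ventricular patterning lists, and HAND2 differed by 0.30 (SE 0.0857) and passed in the patterning list and among the right ventricle and outflow markers. JUP, the plakoglobin gene, differed by 0.35 (SE 0.0941) and passed in the intercalated disc list, and the alpha-1B adrenergic receptor gene ADRA1B differed by -0.48 (SE 0.115) and passed in the adrenergic list. KCNA5 passed in the ion channel list. None of these 6 lists passed with camera. Fibroblast markers had 11 of 14 members lower in septum (adjusted p = 0.0937) and endothelial markers 10 of 12 higher (adjusted p = 0.0937), and neither list passed.

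Within control animals, 0 probe sets passed with limma between septum and free wall, with 1136 at an unadjusted p under 0.05. KCNA5 differed by 0.58 (SE 0.204) and SOCS2 by 0.57 (SE 0.172), each with adjusted p = 0.995 and chosen after their values were seen. Sarcomere genes (17 of 19 higher) and immediate early genes (14 of 15 higher) passed with camera at adjusted p = 0.0259 each (adjusted p = 0.907 with an estimated correlation for both, and 0.153 and 0.917 with fry), with 0 members past adjusted over the list alone. The sarcomere call ended without free wall control array 2 or 3 or septum control array 1 or 3 (adjusted p up to 0.156), and the immediate early call without free wall control array 1 or 2 or septum control array 3 (adjusted p up to 0.720).

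Within paced animals, 0 probe sets passed with limma between septum and free wall, with 1669 at an unadjusted p under 0.05. Other splits of the paced arrays gave 535 to 3871 at that level. KCNA5 differed by 1.47 (SE 0.204, adjusted p = 0.189), SOCS2 by 1.22 (SE 0.172, adjusted p = 0.189) and CCK by -1.36 (SE 0.223, adjusted p = 0.195), all 3 chosen after their values were seen. With probe sets of 1 gene symbol alone, KCNA5 and SOCS2 passed (adjusted p = 0.0498 for both, with a range of 0.0498 to 0.604 over the alternatives of each). Mechanosensing and cytoskeleton genes passed with camera, with 20 of 25 higher in septum (adjusted p = 0.0354, and adjusted p = 0.832 with an estimated correlation and 0.188 with fry). The call ended without free wall paced array 2 or septum paced array 1 or 2 (adjusted p up to 0.426), and with the mean of all probe sets per gene (adjusted p = 0.0724, where the alternatives ran from 0.0149 to 0.832). Adjusted over the list alone, 0 of its members passed. In other lists KCNA5 passed in this way, and so did FHL2 at 0.56 (SE 0.147), GATA6 at 0.71 (SE 0.163), HSPB2, a small heat shock protein gene, at 0.49 (SE 0.119) and ADRA1B at -0.79 (SE 0.162), chosen after their values were seen.

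The effect of pacing was not shown to differ between septum and free wall for any gene. With limma 0 probe sets passed for the difference, with 892 at an unadjusted p under 0.05, and 0 of 45 lists passed with camera, with an estimated correlation or with fry (2 at an unadjusted camera p under 0.05). The effect in septum minus that in free wall was -1.37 for CCK (SE 0.316, adjusted p = 0.999), -0.62 for ABCC4 (SE 0.156) and -0.85 for TP53I13 (SE 0.190). It was 0.91 for FLRT3 (SE 0.195), 0.93 for CD200R1 (SE 0.212) and 0.89 for KCNA5 (SE 0.289). For DOCK8 it was 0.79 in 1 probe set (SE 0.194) and -0.09 in the brightest (SE 0.321). KCNA5 was chosen after its values were seen. Macrophage markers had 12 of 16 members with a higher value in this comparison (adjusted p = 0.515), with MRC1 at 0.71 (SE 0.412) and C1QC at 0.54 (SE 0.288). Across 12217 genes, which are not independent replicates, the effects in free wall and septum had a Pearson correlation of 0.268 and a Spearman correlation of 0.142, and 53.8% of genes had the same sign in both. Free wall and septum arrays can come from the same animals, which raises such a correlation. The Pearson correlation was 0.00469 without the paced arrays numbered 3, 0.168 without the control arrays numbered 1, and 0.478 over genes above the median level.

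Arrays also differed within groups. Free wall paced array 2 had a mean correlation with the other arrays of 0.975, against 0.982 to 0.986 for the rest, and an array weight of 0.274.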

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

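The fits on probe sets with 1 gene symbol, the fits of lists with 1 array left out and the list test with the replicate block in control animals were chosen after the result was seen; the other tests were planned. Of 907 values of the named genes under alternatives with no array left out, 887 kept their direction and side of the threshold, 9 lost and 11 gained a call and 0 turned; of 1170 with an array, or the 2 arrays of a number and arm, left out these numbers were 1122, 43, 2 and 3. The ones that turned were NPPA for pacing averaged over the regions, 0.43 and 0.035 without the control or the paced arrays numbered 3 (range -0.68 to 0.43), and COL3A1, -0.079 without the control arrays numbered 1 (range -0.079 to 0.88). Most of the named values had no call in the main fits and so none to lose. Among the called ones, leaving out arrays ended the call for CCK in 8 of 12 septum fits. For probe set 15342515 it ended in 10 of 12 fits in free wall, 1 of 12 in septum and 3 of 6 averaged over the regions. Between the regions it ended in 10 of 12 for LOC100737875 and 11 of 12 for probe set 15347989. Probe sets past the threshold numbered 1 for pacing in free wall, 2 in septum, 1 averaged over the regions, 0 between the regions of control and of paced animals, 2 averaged over the arms and 0 for the difference between the effects. With the replicate block they numbered 0 in free wall, 1 in septum and 0 between the regions over both arms, where it ended both calls. It moved no other count by over 1.5 times and left the same 2 lists between the regions of control animals. The numbers were taken to pair the control arrays, but the spread in that list test also came from paced arrays joined by number. Paced arrays of the same number did not deviate together, with correlations of 0.03, -0.15 and -0.114, and no paced array correlated best with its own number. Free wall arrays 1, 2 and 3 went best with septum arrays 2, 3 and 1, at 0.477, 0.445 and 0.452, about as high as the control pairs. This may be a hint from the data on which paced arrays share an animal, not the design. Such a match can also come from other traits that arrays share, which was not tested. Free wall paced array 2 and septum paced array 3 had the lowest correlations of their deviation with the mean level (-0.24 and -0.183). Control and paced arrays share only a number. The average over regions joins paced arrays by these numbers, so its errors, p-values and left-out pairs rest on them; its differences with all arrays present do not. With only the 2 groups compared, septum gave 1. With 1 symbol the counts were 0 in free wall, 1 in septum, 0 for pacing averaged, 2 between the regions of paced animals and 5 averaged over the arms; these fits test fewer probe sets. Pacing averaged gave 2 with the animal as a random block and 4 with all 12 arrays and no block. The random block used a correlation of 0.016, so both fits treated the arrays as nearly or fully separate samples. Between the regions over both arms, probe sets above the median, quantile normalization, median centring and eBayes with trend and robust gave 1 each and array weights 4; the cause was not tested. Leaving out arrays gave 0 to 1 in free wall, 0 to 4 in septum (4 without septum paced array 2, 0 without septum paced array 3), 0 to 3 for pacing averaged (3 without the control arrays numbered 1), 0 to 4 between the regions of paced animals (4 without septum paced array 2) and 0 to 3 over both arms (3 without free wall control array 2). List counts fell to 0 with an estimated correlation in all 5 comparisons that had one, and with fry to 0, except 1 (sarcomere) between the regions over both arms; the mean of all probe sets per gene gave 0 in paced animals. Leaving out arrays gave 0 to 2 lists in free wall (2 without free wall control array 1), 0 to 4 in septum (4 without septum control array 2), 0 to 3 for pacing averaged (3 without the control arrays numbered 1 or 2), 0 to 4 in control animals (4 without free wall control array 1 or septum control array 2), 0 to 2 in paced animals (2 without free wall or septum paced array 3), 1 to 5 over both arms (5 without free wall or septum paced array 3) and 0 to 2 for the difference (2 without free wall control array 1). The correlation of the effects of pacing was 0.478 above the median level and 0.00469 to 0.360 with the 2 arrays of a number and arm left out. Only the 2 groups compared was not run for the 3 comparisons that need all groups. Signal over background was not analysed here.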

Other observations

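The tests of free wall paced array 2 for compressed signal and of the unnamed run between the regions for joint movement, and the separate counts of splits that part the control pairs, were chosen after the result was seen. The other tests of explanations in this part were set up before their values were looked at.

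Cell type markers gave a further view of the tissue. Between septum and free wall, markers of lymphocytes (11 of 22 higher in septum), macrophages (10 of 16), smooth muscle and pericytes (6 of 11), adipocytes (6 of 11), atrial myocytes (6 of 12), mesothelium (6 of 8), erythrocytes (5 of 8), Schwann cells (4 of 8), conduction tissue (3 of 9), neutrophils and mast cells (3 of 9) and the right ventricle or outflow tract (3 of 9) had adjusted p of 0.467 or above in camera. For pacing averaged over the regions, fibroblast markers had 10 of 14 members higher and macrophage markers 12 of 16 lower, both with adjusted p = 0.466.

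Other splits of the same arrays were counted for every comparison. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. In that setting the real split gave 1 probe set for pacing in free wall (highest other 1, with 2 splits as large), 2 in septum (highest other 0, 1 split) and 1 for pacing averaged over the regions (highest other 0, 1 split). It gave 0 between the regions of control animals (highest other 0, 10 splits) and 0 between the regions of paced animals (highest other 34, 10 splits). The split with 34, from a real count of 0, may point to a structure of the paced arrays, which was not tested. For lists the real values were 1 for pacing in free wall (highest other 6, 6 splits), 1 in septum (highest other 6, 9 splits), 0 averaged over the regions (highest other 9, 10 splits), 2 between the regions of control animals (highest other 10, 7 splits) and 1 in paced animals (highest other 3, 7 splits). The correlation of 0.268 between the effects of pacing in free wall and septum had a highest other of 0.286, with 2 of 10 splits as large. The splits for this correlation and for pacing averaged over the regions move the arrays of a number and arm together. Paced arrays of the same number did not deviate together. Of 100 splits that reassign arrays freely within each arm, 8 gave at least the 2 probe sets between the regions averaged over both arms (highest other 15) and 40 gave at least the 3 lists (highest other 10), so chance is not excluded for either. For the difference between the effects, 100 of 100 splits gave at least the 0 probe sets (highest other 8) and 100 gave at least the 0 lists (highest other 7). Every split reaches a count of 0, so these shares, and those above for a real count of 0, were fixed in advance and decide nothing. What the split with 8 probe sets follows was not tested.

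Between the regions, most splits put both arrays of a control pair, as taken from the numbers, on 1 side. This can bring differences between the pairs into the comparison. Between the regions of control animals, 4 of the 10 splits part all 3 control pairs. Of these 4, 1 gave at least the 2 lists (highest other 0), against 6 of the 6 splits that keep a pair on 1 side (highest other 10), and 4 splits are too few for a share under 0.05. Averaged over both arms, 40 of the 100 splits part all 3 control pairs. Of these 40, 3 gave at least the 2 probe sets (highest other 6) and 4 at least the 3 lists (highest other 7), against 5 (highest other 15) and 36 (highest other 10) of the other 60 splits. Chance is not excluded in this narrower set either. The split with 15 probe sets parts 1 of the 3 control pairs.

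A run of 15 neighbouring probe sets (6 with 1 symbol, each a LOC gene, 7 with several and 2 without a gene) was lower in paced animals, with 14 of 15 negative, a median of -0.58, 10 at an unadjusted p under 0.05 and 0 past the threshold. Neighbouring means consecutive in the order of probe set IDs, with repeated values left out, and no genome positions were used. It was taken as the run with the largest absolute mean moderated t for pacing averaged over the regions. Its counts follow in part from that choice. A shift of all dim probe sets was argued against, since the other 16504 probe sets in the same range of means had a median change of -0.00833. The highest mean moderated t of any such run was 3.52 in the real split and 2.04 at most in the others, and the 10 splits, of which 1 was as large, are too few for a share under 0.05. Probe sets reading the same transcripts stay open: the deviations of the members within groups had a median pairwise correlation of 0.197, but 14 of 15 have means below every array median, where noise lowers such a correlation. A difference between the animals of the arms, an inherited one included, and an effect of pacing stay open too, and neither was tested.

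A second run of 15 neighbouring probe sets, none with a gene, was lower in septum, with 15 of 15 negative and a median of -0.43, all at an unadjusted p under 0.05 and 0 past the threshold. It was taken in the same way, as the run with the largest absolute mean t between the regions, so these counts too follow in part from the choice. The other 20094 probe sets in the same range of means (2.872 to 9.096) had a median of 0.0117. They too are most of the table, so this value cannot decide on a shift of all probe sets of the same brightness. A step that moves these probe sets together on an array may be part of the pattern, since their deviations within groups had a median correlation of 0.846 (0.737 to 0.873 with 1 array left out). Of 100 splits 5 had a run as large (3.71 in the real one, 4.13 at most in the others), so chance is not excluded. Array handling that differed between the regions and a difference between the tissues stay open, since no source used here says what these probe sets measure or in which order arrays were run.

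Free wall paced array 2 lay apart from the other arrays. A compressed signal may contribute, since its deviation from its group had a correlation of -0.24 with the mean level across probe sets, the lowest of the 12 arrays (others -0.183 to 0.145), but the value lies between the bounds set for and against. It was the highest of all arrays in 3 of 13 marker lists and the lowest in 0, where other arrays were highest or lowest in up to 5. The 3 lists were mesothelium (score 0.37, next array 0.17), erythrocytes (0.23, next 0.15) and adipocytes (0.22, next 0.15). This leaves another cell composition open as well. A biological difference of the sampled tissue stays open and was not tested.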
